A study of Homo sapiens with 2 samples.

How the data were processed

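Total RNA from 2 stable populations of the melanoma cell line MeWo was measured on 2 one-colour expression microarrays, 1 array per group. One population carried a scrambled control hairpin (scr-shRNA) and the other a hairpin against STARD3 (STARD3-shRNA). Per the labels' protocols, RNA was extracted with TRIzol, cleaned on a column kit, amplified with a low-input Agilent kit and labelled with Cy3. The series description names an Affymetrix chip, while the scanner files, the labelling kit and the probe identifiers belong to an Agilent 60-base array, and the files were read as Agilent data. The labels give no repeat of either population.

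The deposited scanner files hold spot intensities on a linear scale. Per the file headers, they were made with Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.5.1.1. Per the file headers, the processed intensity is background-subtracted and detrended across the array, with small values replaced by surrogates, and it is not scaled between arrays. The authors also deposited a table of processed intensity values for 50599 probes. Its scale was settled against the scanner values: the log2 of each column followed its own array with Pearson r of 0.9997 and 0.9996 across probes, the median was 23.5 in both columns, and 99% of the sorted values were equal. Columns with nearly equal sorted values are what quantile normalization gives, but the step itself is not stated in the sources used here. The table was used as an alternative. The flags of Feature Extraction for control spots, outliers, saturation and signal well above background were used as deposited, and spot positions came from the same files.

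The main values were computed from the processed intensity as log2 minus the array's 75th percentile over non-control probes. Spots with an outlier flag were left out, 263 on the control array and 269 on the STARD3-shRNA array, and the remaining spots of a probe were averaged on the log2 scale. Neither array had a saturated non-control spot. Both arrays were on the same slide and scan, so slide and scan do not separate the groups. Differences in culture, extraction, amplification or labelling cannot be told apart from the groups, since each group is 1 sample.

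Probes were named through a table of RefSeq genes for GRCh38.p14, used for names only. Of 50599 probes, 28174 matched by accession, 2618 by symbol and 620 by a synonym that belongs to a single gene, and 19187 had no match. The matched probes gave 21363 genes. A gene took its probe with the highest mean signal, with preference for probes well above background on both arrays. On this basis 14549 genes were measured on both arrays, 1409 on a single array and 5405 on neither. Coordinates are those of the probes in the files, on hg19. No genome sequence or gene annotation on hg19 was used here, so exons and UTRs are not given.

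Differences are log2 values of the STARD3-shRNA array minus the control array. No test, p-value or between-culture error exists with 1 array per group, and genes were named by size, with a limit of 2-fold. For a gene well above background on a single array, the difference is a lower bound, written as "at least N-fold". It sets the bright array's value against the higher of the dim probe's own value and the lowest value among probes well above background on the dim array. Where the dim probe's own value is the higher, the result is still counted as a bound but is only the plain difference. The only repeat measurement is spots of the same probe on the same array. Across 641 probes with 5 or more usable spots on each array, the spot-to-spot SD of a single-spot difference was 0.20 on the log2 scale for the dimmest of 3 equal groups by signal, 0.08 for the middle group and 0.06 for the brightest group. An SD given beside a gene or probe is that of its group by mean signal over both arrays, and was not measured on that gene. For genes it is divided by the square root of the number of spots. This SD covers neither culture, extraction nor labelling.

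Gene lists (40) were fixed before the data were examined. Each list's median was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and is reported with its percentile. A list is said to lie above or below the random lists when it falls outside their middle 95%. About 2 of 40 lists would do so by chance. The percentile describes these 2 arrays and is not a test of the conditions. Lists with fewer than 5 measured genes get no percentile.

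The genes named in the text follow a rule set before the data were examined. It takes STARD3, then the 12 highest and the 12 lowest genes at least 2-fold different with all measured probes moving the same way. It adds the 3 largest lower bounds in each direction, and up to 4 members per list with the largest absolute difference. Unnamed loci, open reading frames, XIST and Y-linked genes were left out. Other members of a list that are named were chosen after their values were seen.

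Alternatives set before the data were examined were median centring, quantile normalization, loess after centring, normexp background correction with an offset of 50, the authors' table, no filter on dim probes, brighter probes only, the mean of a gene's probes, removal of saturated probes, and limits of 1.5-fold and 3-fold. Scaling on the 8 usable E1A spike-in probes, and subtraction of the median of the other genes in each 10 Mb window, were added after the data were seen. Lists under the alternatives were set against 2000 random lists.

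The procedure was tested on simulated data for the same comparison, with 15673 genes and spot-to-spot error, 200 of them changed. The 2-fold limit took 0% of genes changed 1.5-fold, 46% of those changed 2-fold and 100% of those changed 3-fold or 8-fold. No unchanged gene passed it, but the simulated spot-to-spot error was far below that limit, so this outcome was set in advance. Differences of culture, extraction and labelling were not simulated, so false 2-fold calls from them cannot be judged. Lists of 20 genes shifted by 0.3 lay outside the random range in 82% of draws when the spread between genes was that of the real data, and unshifted lists in 4% of draws. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for normexp.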

Results

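The series asked how a hairpin against STARD3 alters gene expression in MeWo, an established human melanoma line that makes pigment. STARD3 is a sterol-binding protein of late endosomes that carries cholesterol at contacts with the endoplasmic reticulum. RNA from cells with stable scr-shRNA and from cells with stable STARD3-shRNA was hybridised to 1 array each. Of 50599 probes, 28866 (57.1%) were well above background on the control array and 26561 (52.5%) on the STARD3-shRNA array. The signal at the 75th percentile was 460.4 on the control array and 347 on the STARD3-shRNA array, a 1.33-fold gap on the linear scale that the scaling removes. Across the 25753 probes well above background on both, Pearson's r of the log2 values was 0.98. Genes are not independent replicates, and the number of arrays, 1 per group, limits the precision of every value that follows.

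STARD3 itself was only slightly lower on the STARD3-shRNA array. Both of its probes, at 37819508 to 37819567 and 37819663 to 37819722 on chromosome 17 (hg19), gave a log2 difference of -0.37, or 1.29-fold lower, with a spot-to-spot SD of 0.08 and 0.06. The sequence of the brighter probe is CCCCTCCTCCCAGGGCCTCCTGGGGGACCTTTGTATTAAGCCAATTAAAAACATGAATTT, and its signal was 13612 on the control array and 7950 on the STARD3-shRNA array. Without any scaling the difference of that probe was -0.78, or 1.71-fold. The direction follows the labels, but a difference of this size does not settle whether they are right, on which the sign of every other value rests: 16.2% of the 14549 measured genes were lower still, and the middle of all genes ran from -0.22 to 0.32 (quartiles). Genes beside STARD3 at 17q12, fixed as a list of genes the hairpin does not target, had a median of -0.27 over 11 measured genes, percentile 2.02 of the random lists. MED1 differed by -0.60 on its brighter probe and by -0.17 on its other measured probe. MIEN1 differed by -0.38, GSDMB by -0.35 and PGAP3 by 0.52. The list was within the random lists in 6 of the 8 other settings that could move it.

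Between the arrays, 975 of 14549 genes (6.70%) differed at least 2-fold, with 513 higher and 462 lower on the STARD3-shRNA array. The share of higher genes was 52.6% (exact binomial 95% interval 49.4 to 55.8, which covers counting error only). That split depends on the scaling: on the spike-in probes it became 319 higher and 851 lower, 27.3% higher, because this scaling shifts every difference by -0.27 and moves the median of all genes from 0.06 to -0.21. The values given for genes and lists are relative to the 75th percentile, and the same shift applies to each of them. List medians above 0 by less than the size of that shift turn below 0 under it. A further 212 genes were at least 2-fold higher and 232 at least 2-fold lower by a lower bound. Of 195 genes past the limit with several measured probes, 181 (92.8%) had all probes moving the same way, but only 100 had all probes past 2-fold. With 1 array per group there are no replicates, and the spot-to-spot SD of a difference was 0.20 for dim, 0.08 for middle and 0.06 for bright probes.

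**Figure D1:**
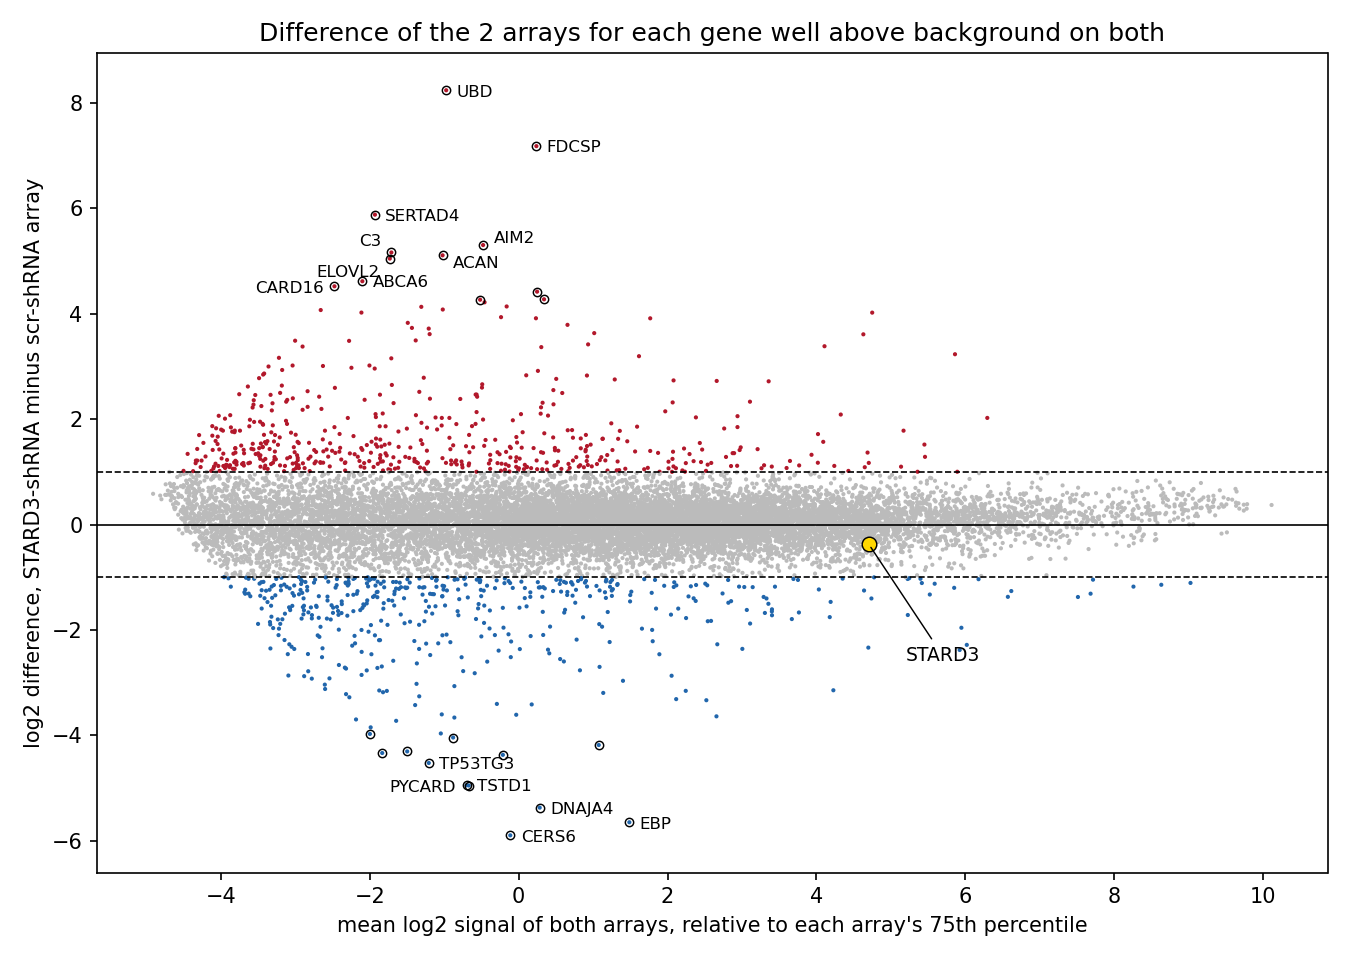
Log2 difference of the 2 arrays (vertical axis) against mean log2 signal relative to the 75th percentile (horizontal axis) for the measured genes. XIST, TSIX and Y-linked genes are not drawn. Dashed lines lie at 2-fold, with red for genes at least 2-fold higher and blue for genes at least 2-fold lower. Black rings mark the 12 highest and 12 lowest genes of the fixed rule. STARD3 (yellow) lies at -0.37, inside the grey mass of genes under 2-fold, while UBD lies at 8.25 and CERS6 at -5.90.

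The genes with the largest positive differences included inflammatory and immune genes. UBD, which encodes the ubiquitin-like protein FAT10, was 304-fold higher on the STARD3-shRNA array (log2 8.25, spot-to-spot SD 0.20). FDCSP, a secreted peptide, was 145-fold higher, and SERTAD4 59.0-fold. AIM2, a sensor of cytosolic DNA, was 39.6-fold higher, complement C3 35.9-fold, and the proteoglycan gene ACAN 34.6-fold. ELOVL2, an elongase of polyunsaturated fatty acids, was 33.1-fold higher and the transporter gene ABCA6 24.6-fold. CARD16 was at 4.52 on the log2 scale, but its sequence is close to that of CASP1 and the value is uncertain. The transcription factor IRF4 was 21.4-fold higher, the matricellular gene CCN5 19.4-fold and the chemokine CXCL8 19.3-fold. On the control array UBD was at -5.10 relative to the 75th percentile, SERTAD4 at -4.87 and CARD16 at -4.74. These lie near the lowest signal well above background there (12.35 on the linear scale), so their folds are uncertain. ABCA6, C3 and ELOVL2, from -4.41 to -4.26, were also dim on that array. The chemokine CCL2 was 111-fold higher and the NF-kB target BIRC3 82.3-fold, both as plain differences from a dim control value and not strict bounds. By its lower bound, NKAIN2 was at least 37.0-fold higher. Other probes were less clear for some of these genes. A second C3 probe gave 1.89 on the log2 scale, a second ACAN probe gave -0.69 and was not well above background on the STARD3-shRNA array, and a second NKAIN2 probe gave -3.41, also dim on that array.

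The genes with the largest negative differences had diverse functions. CERS6, a ceramide synthase, was 59.7-fold lower (log2 -5.90), and its second probe was also lower but dim on the STARD3-shRNA array. EBP, the sterol isomerase of the late cholesterol pathway, was 50.3-fold lower (log2 -5.65, spot-to-spot SD 0.08), on a single probe at 48386942 to 48387001 on chromosome X. Its value on the STARD3-shRNA array was -1.34, and dim probes on that array had a spot-to-spot SD of 0.15, so 0.08 may be too small. The co-chaperone gene DNAJA4 was 41.5-fold lower, PYCARD, the adaptor of inflammasomes, 31.0-fold, and TSTD1 30.9-fold. TP53TG3, which exists in near-identical copies and is therefore uncertain, was 23.1-fold lower, but only -1.63 on the log2 scale on its other measured probe. EPDR1 was 20.7-fold lower, the phospholipase gene PLAAT1 20.2-fold and PNMA8A 19.8-fold. The noncoding RNA LINC01502 was 18.2-fold lower, BIRC7, an inhibitor of apoptosis, 16.5-fold, and PERM1 15.7-fold. By lower bounds, CREG2 was at least 110.5-fold lower and PGAP4 at least 54.5-fold. The vesicular nucleotide transporter gene SLC17A9 was 90.7-fold lower, as a plain difference from a dim value on the STARD3-shRNA array and not a strict bound.

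Sterol synthesis genes were lower as a group. The list of cholesterol synthesis and uptake had a median of -0.47 over 23 measured genes, at percentile 0 of the random lists, and 20 of the 23 were below 0 (22 with the spike-in scaling). Of these, 5 were at least 2-fold lower, none at least 2-fold higher and 18 under 2-fold. Beside EBP, the SREBP regulator INSIG1 was at -1.31, the isoprenoid isomerase IDI1 at -1.18, HSD17B7 at -1.13 and MSMO1 at -1.07. MSMO1, and the other list members named outside the naming rule, were chosen after their values were seen. The transcription factor SREBF2 was at 0.20. Fatty acid synthesis genes had a median of -0.36 over 18 genes (percentile 0.01), with none past 2-fold. The desaturase FADS1 was at -0.67, the elongase ELOVL6 at -0.58, and fatty acid synthase FASN and the acyl-CoA synthetase ACSL3 at -0.55 each. The position of both lists was the same in 8 of the 8 other settings that could move it, which leaves out shifts of all genes alike.

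Lists of other lipid pathways had medians nearer 0. Sphingolipid metabolism had a median of -0.14 over 26 genes (percentile 1.44), with 1 gene at least 2-fold lower, CERS6, and 1 at least 2-fold higher, CERS4 at 1.88. CERS1 was at -0.94 and the acid ceramidase ASAH1 at -0.58. With brighter probes only, the median was -0.067 and the list was within the random lists (percentile 9.65). The START family, relatives of STARD3 in their lipid-binding domain, had a median of -0.26 over 12 genes (percentile 1.87), but 0.035 when only brighter probes were kept, and it was within the random lists in 5 of those 8 settings. ACOT12 was at -1.54, PCTP at -0.73, STARD8 at -0.72 and STARD13 at 0.99, and STARD6 was higher by a bound past 2-fold. LXR targets and sterol efflux genes lay within the random lists (median 0.18, 12 genes, percentile 86.0), and above them without the filter on dim probes (median 0.35, 15 genes). Among them APOC1 was at -1.34, ABCA1, the cholesterol exporter, at 1.20 and PLTP at 0.70, and the lipoprotein gene APOE was 2.14-fold higher. Endosomal sterol transfer and contact site genes had a median of 0.07 (29 genes, percentile 58.1), with GRAMD1C at -1.22, OSBPL5 at 0.99, CAV1 at 0.95 and OSBPL10 at 0.91. Steroid synthesis and mitochondrial cholesterol genes had a median of -0.05 (14 genes, percentile 10.4). There ACBD3 was at -0.41, CYP27A1 at -0.37, TSPO at 0.31 and VDAC1 at 0.30, and AKR1C1 and AKR1C3 were lower by bounds past 2-fold. Lysosome genes had a median of 0.02 (36 genes, percentile 19.2) and none past 2-fold, with GAA at -0.97, CTSD at 0.90, LAMP2 at 0.64 on its brightest probe but -0.14 on another, and CTSK at -0.61. Autophagy genes had a median of 0.13 (25 genes, percentile 79.3). TP53INP1 was at 2.83 on its brighter probe but 0.30 on another, ULK2 was at -1.09, SQSTM1 at 0.89 and WIPI1 at -0.66.

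NF-kB targets and cytokines had the highest median of the 40 lists. It was 1.52 (2.87-fold) over 17 measured genes at percentile 100, and all 17 were above 0, with the spike-in scaling as well. Of these, 11 were at least 2-fold higher, and BIRC3, CCL2 and IL1B were higher by bounds past 2-fold. CXCL8 was at 4.27, the adhesion molecule ICAM1 at 3.92, and the neutrophil chemokines CXCL1 and CXCL2 at 3.61 and 3.20. RELB, a subunit of NF-kB, was at 2.72, the inhibitor NFKBIA at 1.72 and LIF at 2.08. Fibroblast markers also lay above the random lists, with a median of 1.13 over 7 genes, 4 of them above and 3 below 0. The interferon response list did not follow, with a median of -0.02 over 22 genes (percentile 24.7). It held 2 genes at least 2-fold higher, IRF1 at 1.46 and IFIT2 at 1.16, and 3 at least 2-fold lower, IFI27 at -3.32, USP18 at -1.63 and MX1 at -1.28. Antigen presentation genes had a median of 0.39 over 18 genes (percentile 99.9). TAPBP was at 1.07 and the immunoproteasome subunits PSMB8 and PSMB9 at 1.41 and 1.04, while the class II gene HLA-DPB1 was at -1.63. Of the 18 genes, 14 lie between 20 and 40 Mb on chromosome 6, where the 278 other measured genes had a median of 0.18 (percentile 99.99). Near-identical HLA genes share probe sequence, so their single values are uncertain.

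**Figure D2:**
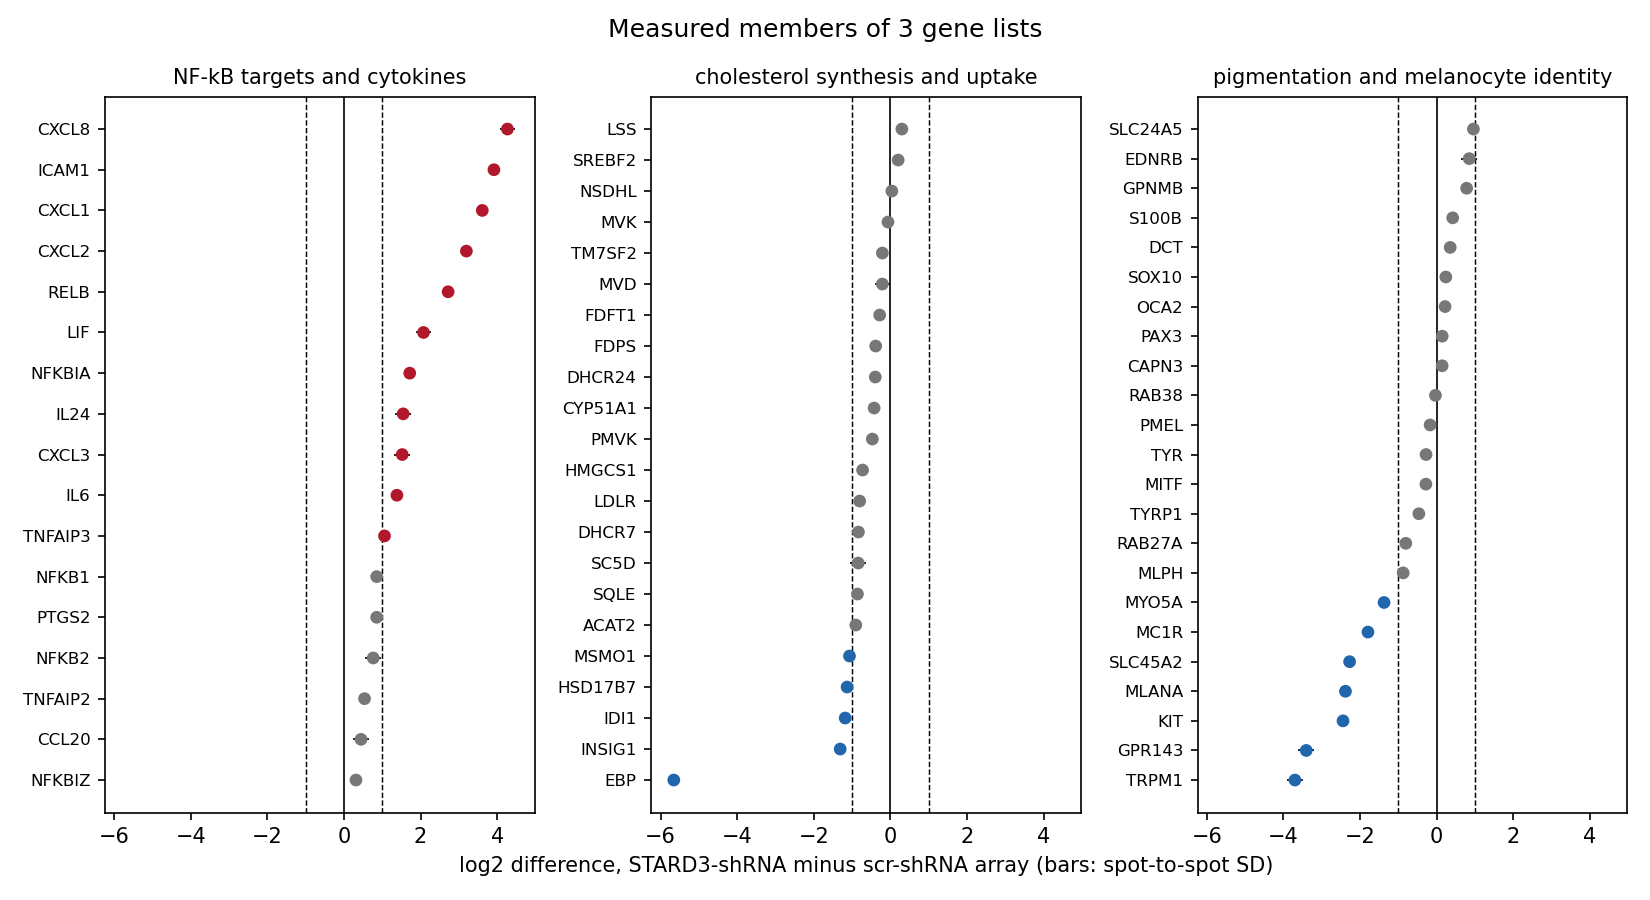
Log2 difference, STARD3-shRNA minus scr-shRNA array, of the measured members of 3 lists (1 cholesterol gene is not drawn), with bars for the spot-to-spot SD of each gene's signal group, dashed lines at 2-fold and red or blue for genes past it. All 17 NF-kB targets and cytokines lie above 0, with the spike-in scaling as well, while 20 of 23 cholesterol genes lie below 0 (22 with that scaling) and the pigmentation genes spread from TRPM1 at -3.70 to SLC24A5 at 0.96.

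Listed melanocyte genes ranged from far lower to somewhat higher. The pigmentation and melanocyte identity list had a median of -0.28 over 23 genes (percentile 0), with 7 at least 2-fold lower, none at least 2-fold higher and 16 under 2-fold, and 9 of the 23 were above 0 (5 with the spike-in scaling). The cation channel TRPM1 was at -3.70, the melanosomal receptor GPR143 at -3.41, the receptor tyrosine kinase KIT at -2.45 and the melanosomal protein MLANA at -2.38. SLC45A2 was at -2.27, MC1R at -1.80 and MYO5A at -1.38. MITF, the melanocyte master regulator that controls many of these genes, was at -0.28, SOX10 at 0.24 and PMEL at -0.17, while MLPH was at -0.88, RAB27A at -0.81, SLC24A5 at 0.96, EDNRB at 0.85 and GPNMB at 0.78, or -0.12 on its other probe. Markers of dedifferentiated melanoma had a median of 0.60 over 15 genes (percentile 100), with 10 above and 5 below 0. TWIST2 was at 2.98, IL6 at 1.38, TNC at 1.12 and LOXL2 at 0.74, and WNT5A was higher by a bound past 2-fold. IL6 also belongs to the NF-kB list, TWIST2 to the fibroblast list, and TNC and LOXL2 to the matrix list. The median of the neural and Schwann cell markers was -0.0039 over 14 genes (percentile 22.4), with the neurofilament genes NEFL at -3.15 and NEFM at -2.12, TUBB3 at -1.33, EGR2 at -1.16 and MAP2 at 1.19. The list lay below the random lists in 2 of the 8 settings that could move it.

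Cancer-testis antigens, germline genes that many melanomas express, had a median of 0.99 over 12 genes (percentile 100). Of these, 5 were at least 2-fold higher, and 10 were above 0, or 8 with the spike-in scaling. CTAG2 was at 3.38, MAGEA1 at 1.45, CSAG3 at 1.42, CSAG2 at 1.14 and CSAG1 at 1.12. MAGEB2 was at -1.54, and MAGEC2 was lower by a bound past 2-fold. These families hold near-identical copies, so single values are uncertain. Of the 11 list members with coordinates, 7 lie between 150 and 160 Mb on chromosome X, with a median of 1.12, where the 65 other measured genes had a median of 0.29 (percentile 100). With the median of each gene's window removed, the list median was 0.67.

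Signalling and matrix lists gave smaller differences. TGF-beta and YAP targets had a median of 0.30 over 17 genes (percentile 98.4), with SMAD7 at 1.47, CCN2 at 1.17, CCN1 at 0.97 and ID1 at 0.88. MAPK output and immediate early genes had a median of 0.25 over 25 genes (percentile 98.9), which turned to -0.026 with the spike-in scaling. PHLDA1 was at 1.21, IER3 at 1.17, FOSB at 0.89 and EGR2 at -1.16, and the list was within the random lists in 4 of the 8 settings that could move it. Extracellular matrix and remodelling genes had a median of 0.27 over 28 genes (percentile 99.1), which turned to -0.0043 with the spike-in scaling. With brighter probes only, the median was 0.20 and the list was within the random lists (percentile 91.8). DCN was at 1.70, MMP16 and MMP8 at 1.14 each, TNC at 1.12, and the plasminogen activator PLAU at -2.19. Integrins and focal adhesion genes lay within the random lists (median 0.19, 26 genes, percentile 93.9), although ITGA7 was at -3.34, ITGA2 at -1.24, ITGB3 at -1.19 and ITGA1 at 1.11. Cadherins and EMT transcription factors had a median of 0.0030 (14 genes, percentile 29.0). OCLN was at 0.82, CDH2 at 0.68, L1CAM at 0.53 and CTNND1 at 0.43, and CDH1 and CDH3 were lower by bounds past 2-fold. The ERBB and PI3K list had a median of 0.10 (23 genes, percentile 65.9), with ERBB4 at 1.26, PIK3R3 and IRS1 at -0.64 and 0.64, and NRG1 lower by a bound past 2-fold.

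Markers of other cell types were sparse. Of 16 fibroblast markers, 7 were measured on both arrays, with a median of 1.13 (percentile 100). TWIST2 was at 2.98, the protease gene FAP at 2.75, DCN at 1.70 and S100A4 at 1.13, and ACTA2 was higher by a bound past 2-fold. The other 3 measured markers were lower, LUM at -0.33, FBLN1 at -0.44 and MFAP5 at -0.54, although 1 of the 3 FBLN1 probes gave 0.13. With brighter probes only, 4 markers remained and no percentile was given. DCN is also in the matrix list and TWIST2 in the dedifferentiated list, so these lists are not independent. The collagen genes COL1A2 and COL3A1 were not well above background on either array, and COL1A1 only on the control array. Keratinocyte and epithelial markers had a median of -0.10 (5 genes, percentile 23.9), with SFN and KRT18 at 0.42 each, LAMB3 at -0.41 and KRT10 at -0.14, KRT14 and KRT19 higher and CDH1 and DSP lower by bounds past 2-fold. Endothelial markers had a median of 0.37 (5 genes, percentile 87.6), with KDR at 1.43, VWF at -0.76 on 1 probe and 0.75 on another, CDH5 at 0.61, ENG at 0.37 and FLT1 higher by a bound past 2-fold. Leukocyte markers had a median of 0.24 (11 genes, percentile 81.3), with CD3E at 1.87, CD68 at -0.55, TYROBP at 0.52 and CD8A at 0.43. On the control array CD3E was at -5.05, near the lowest signal well above background, so its difference is uncertain.

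Proliferation and cell death lists lay within the random lists. G1/S genes had a median of 0.10 (24 genes, percentile 65.5) and G2/M genes of -0.05 (26 genes, percentile 7.16), with no member of either past 2-fold. MCM10 was at -0.57, MCM3 at 0.50, and CCNE2 and E2F1 at 0.48 each. MKI67 was at -0.48, KIF23 at -0.26, CCNB1 at 0.25 and CCNB2 at -0.24. Other measured probes went the other way for CCNE2 (-0.26), MKI67 (0.26) and CCNB1 (-0.11). The p53 targets had a median of 0.04 (23 genes, percentile 48.2), with TP53INP1, shared with the autophagy list, at 2.83, the death receptor FAS at 1.95, PHLDA3 at -1.55 and POLH at 0.90. Apoptosis regulators had a median of 0.09 (25 genes, percentile 69.0), with BIRC7 at -4.04, BIRC2 at 1.05, BCL2L11 at 0.58, BIK at -0.56 and BIRC3, shared with the NF-kB list, higher by its bound. RNA interference machinery genes, listed because a hairpin uses them, had a median of -0.04 (13 genes, percentile 27.6). AGO4 was at -0.68, PRKRA at -0.45, TARBP2 at 0.32 and DGCR8 at 0.30.

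Of the stress and metabolic lists, only the unfolded protein and amino acid response lay outside the random lists. Its median was -0.18 over 25 genes (percentile 0.21), with none past 2-fold. SLC7A11, the cystine transporter gene, was at -0.93, ATF3 at 0.75 with its 4 probes from -0.28 to 0.75, DNAJC3 at -0.61 and CHAC1 at -0.56. Heat shock genes had a median of -0.06 (15 genes, percentile 4.97), with CRYAB at -1.98, HSPB8 at -0.57, HSPA8 at 0.31 and DNAJA1 at 0.27. NRF2 targets and metallothioneins had a median of 0.14 (20 genes, percentile 64.7), with MT1F at -1.36, the shared SLC7A11 at -0.93, HMOX1 at -0.82 and OSGIN1 at -0.62. Hypoxia and glycolysis genes had a median of -0.01 (23 genes, percentile 14.7). The lipoprotein lipase inhibitor ANGPTL4 was at 3.72, ADM at -2.18, PFKP at -0.83 and PFKFB4 at -0.70, and CA9 was higher by a bound past 2-fold. Oxidative phosphorylation genes had a median of 0.18 (27 genes, percentile 73.6), with PPARGC1A at -1.05, COX7C at 0.53, CYC1 at 0.52 and NDUFA1 at 0.47.

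Ribosomal protein genes were higher by an amount that depended on the scaling. Their median was 0.47 (1.38-fold) over 35 genes at percentile 100, none was past 2-fold, and 35 of 35 were above 0, or 31 with the spike-in scaling. After quantile normalization the median was 0.12 with 25 genes above and 9 below 0, and after loess 0.14 with 27 above and 8 below 0. RPL37 was at 0.83 on its brighter probe but -0.18 on another, and RPS3 and RPL3 were each at 0.68. Replication-dependent histone genes had a median of 0.11 (25 genes, percentile 70.7), with H2BC21 at -1.28, H2BC6 at -0.60 and H2BC12 at 0.53. Housekeeping genes had a median of 0.15 (26 genes, percentile 68.5), with IPO8 at 1.03, EEF1A1 at 0.63, PGK1 at 0.48 and HPRT1 at 0.39. In all, 9 lists lay above, 7 below and 24 within the random lists.

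**Figure D3:**
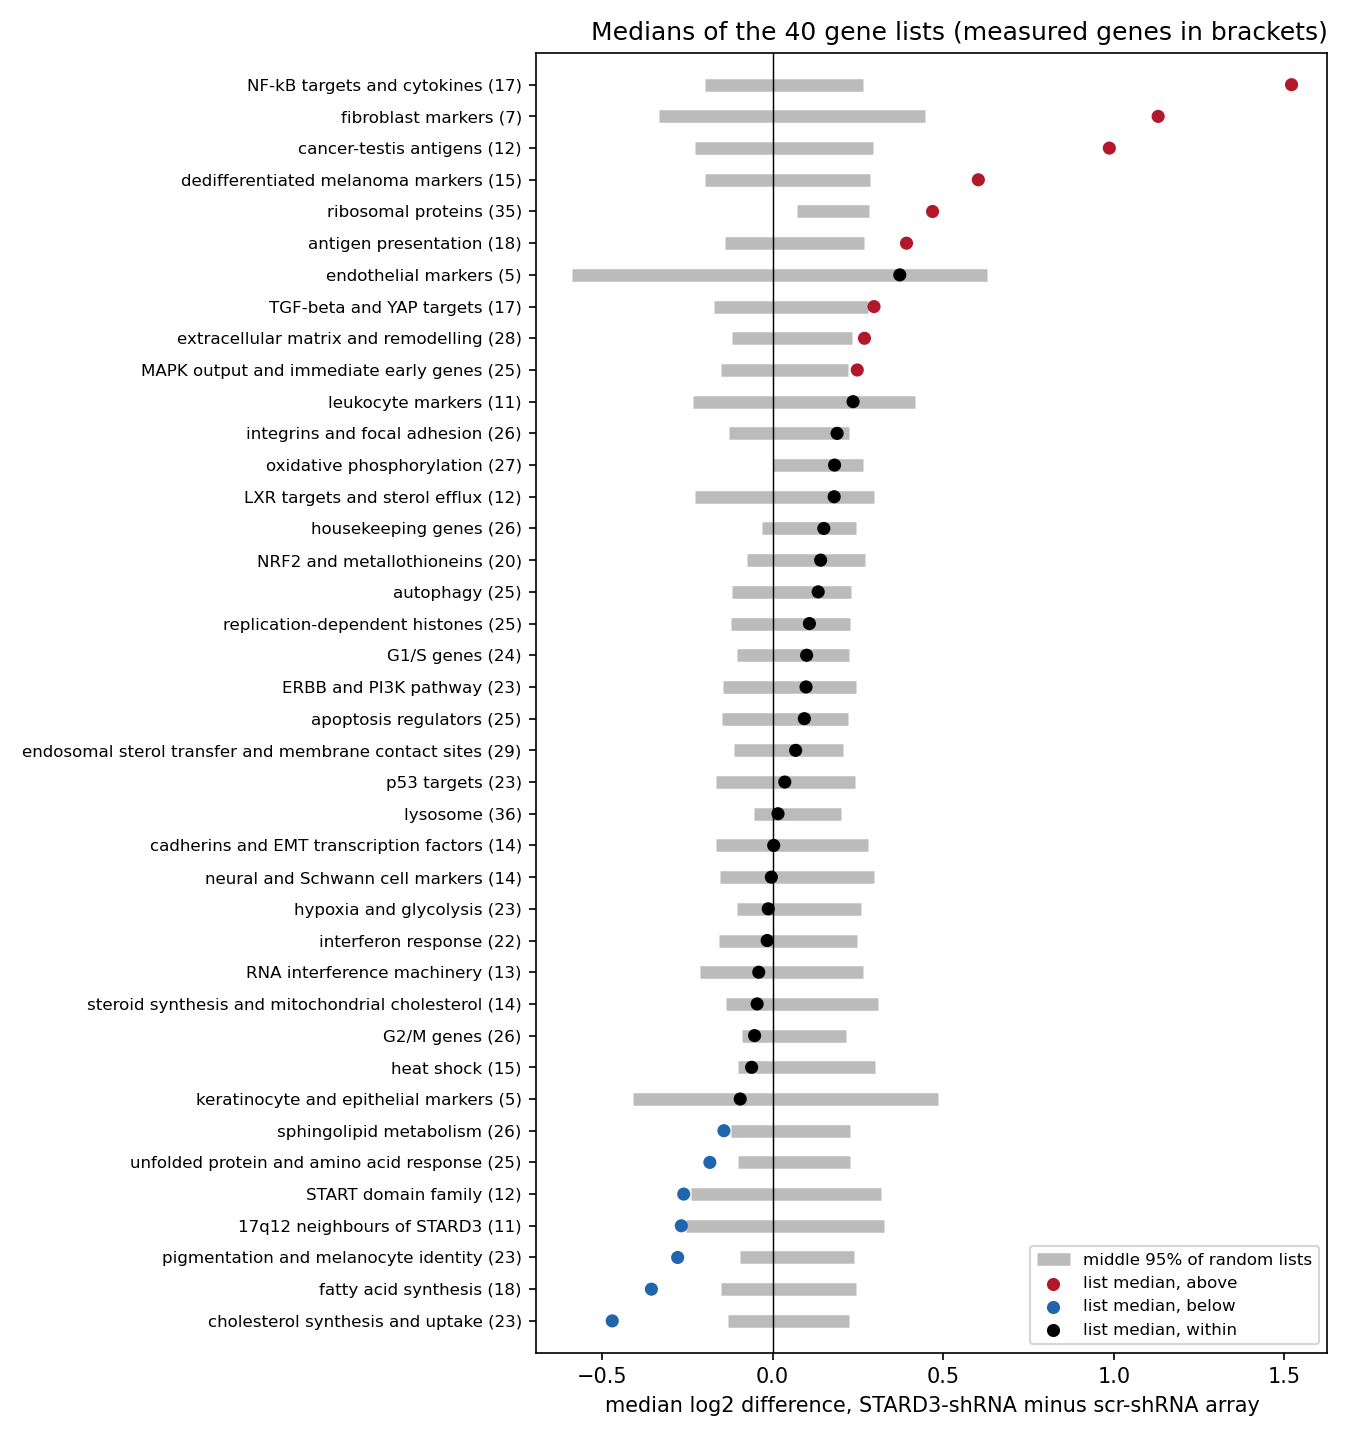
Median log2 difference, STARD3-shRNA minus scr-shRNA array, of each of the 40 gene lists (points, with the number of measured genes in brackets) over the middle 95% of 10000 random lists matched in size and signal (grey bars). The NF-kB list lies farthest to the right at 1.52 and the cholesterol list farthest to the left at -0.47, while the medians of the MAPK and matrix lists, and of lists within the grey bars that lie little above 0, turn below 0 with the spike-in scaling.

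Differences were shared by neighbouring genes along the chromosomes. Of 249 windows of 10 Mb with 20 or more measured genes, 56 had a median above and 74 a median below the middle 95% of random lists, where 12.5 in total would be outside by chance. Window medians ran from -0.55, between 10 and 20 Mb on chromosome X, to 0.42, between 40 and 50 Mb on chromosome 5. Under the main scaling, windows of the same sign often lay in long runs. Every such window of chromosome 1 was below 0, and its 1479 genes had a median of -0.12 (percentile 0). On chromosome X, windows up to 60 Mb were below 0 and those from 70 Mb above 0. Windows of chromosome 8 were below 0 up to 90 Mb and above 0 beyond it. Chromosome 3 as a whole lay within the random lists (median 0.06, percentile 55.1). On chromosome 17 the window from 10 to 20 Mb had a median of 0.30 over 67 genes, and the window from 50 to 60 Mb one of -0.32 over 49 genes. STARD3 lies in the window from 30 to 40 Mb, whose 125 genes had a median of -0.12. EBP lies in the window from 40 to 50 Mb on chromosome X, whose 66 genes had a median of -0.45. With the median of the other genes in its window removed, STARD3 was at -0.25.

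**Figure D4:**
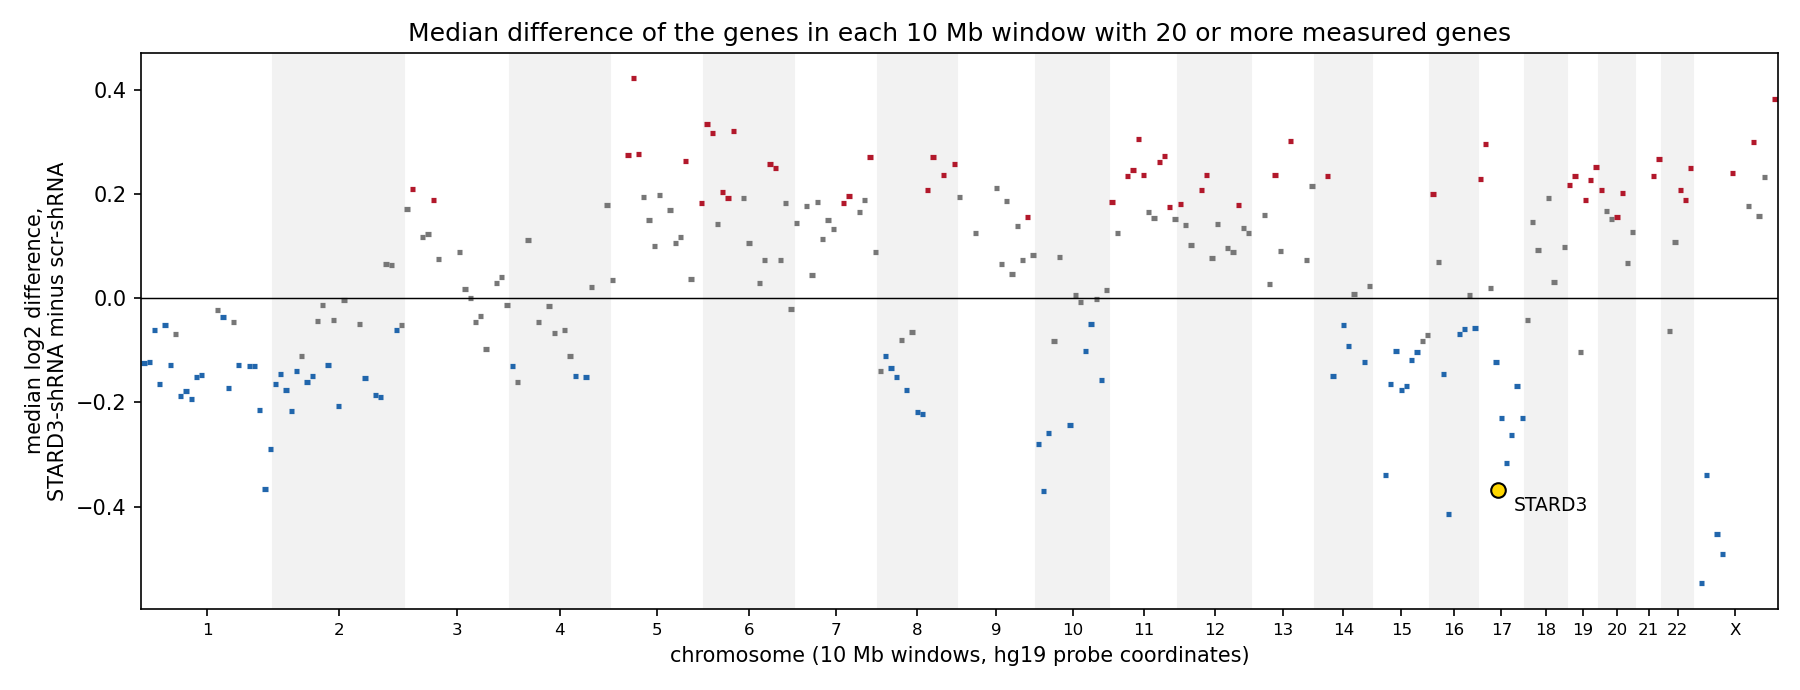
Median log2 difference, STARD3-shRNA minus scr-shRNA array, of the genes in each 10 Mb window with 20 or more measured genes (dashes), along hg19 chromosomes 1 to 22 and X, with red above and blue below the middle 95% of random lists and grey within it. STARD3 (yellow point) lies at -0.37 over a window with a median of -0.12, and window medians range from -0.55 to 0.42.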

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

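Transcripts on the array without a gene in the reference table were outside the comparison of named genes, and part of them differed between the arrays. Of 4747 such transcripts measured on both arrays, 201 were at least 2-fold higher on the STARD3-shRNA array than on the control array and 156 at least 2-fold lower. The share that differed was 7.52%, beside 6.70% of named genes. These shares were not matched on signal, on which the share past 2-fold depends, so the gap between them cannot be read. The transcripts carry no gene name here, and no explanation was tested.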

How the results depend on the processing

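Spike-in scaling and removal of the window median were chosen after the data were seen. No paired analysis was possible because each group has 1 array. Removing saturated probes left out 0 probes, so that setting tested nothing, and median centring and spike-in scaling shift all genes alike, so they cannot move a list among the random lists. STARD3 stayed lower in every setting that changed a value, at -0.45 after loess, -0.64 with the spike-in scaling and -0.25 with the window median removed. The counts of genes at least 2-fold higher and lower were 263 and 262 with normexp, 1400 and 1350 without the filter on dim probes, 166 and 160 with brighter probes only, and 319 and 851 with the spike-in scaling. They were 1491 and 1239 at 1.5-fold and 193 and 189 at 3-fold. The filter settings changed the number of genes tested from 14549 to 21363 without the filter and to 9405 with brighter probes only. The counts changed by more than in proportion, so gene number alone does not account for them, and the share past 2-fold was higher with dim probes included. The limit itself accounts for the fold settings, and the spike-in scaling shifts every difference by -0.27. The offset of normexp shrinks the differences of dim genes by construction, and 263 of the 513 higher and 252 of the 462 lower genes remained under it. The share of higher genes was 47.7% after loess, 27.3% with the spike-in scaling and 48.4% with the window median removed, and the cause of the first and last was not tested. Among lists outside the random lists, medians that changed sign were the MAPK list (-0.026) and the matrix list (-0.0043) with the spike-in scaling, and the START list (0.035) with brighter probes only. Medians of lists within the random lists also turned below 0 with the spike-in scaling, among them LXR (-0.09), autophagy (-0.14), integrins (-0.08), oxidative phosphorylation (-0.09), NRF2 (-0.13), housekeeping (-0.12), ERBB (-0.18) and G1/S (-0.17), and some lists near 0 changed sign in other settings. For lists outside the random lists, the spike-in shift also moved most medians by over 1.5 times with their sign kept, such as cholesterol (-0.74), fatty acid synthesis (-0.63), dedifferentiated markers (0.33), antigen presentation (0.12) and TGF-beta and YAP targets (0.024). In the other settings, medians of these lists that did so and kept their position were those of ribosomal proteins after quantile normalization (0.12), after loess (0.14) and in the authors' values (0.12), of NF-kB targets with normexp (0.97), of pigmentation (-0.45) and the unfolded protein response (-0.28) after loess, of pigmentation (-0.17) and antigen presentation (0.73) with brighter probes only, of antigen presentation (0.26) with the window median removed, and of cancer-testis antigens (0.61), matrix (0.46) and fibroblast markers (0.60) without the filter on dim probes. Apart from the shift of the spike-in scaling, the cause was not tested. For the 177 named genes with values on both arrays, 1705 values were recomputed. Of these, 1173 stayed within the spot-to-spot SD and 532 moved by more, and 0 genes past 2-fold changed sign. Differences of dim genes are the least certain, since their spot-to-spot SD of 0.20 is over that of bright genes, 0.06.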

Other observations

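The tests of scaling, of the chromosomal neighbours of STARD3 and of an interferon response were chosen only after the results were seen. Limits of the other tests were set before their outcomes were known. Those tests, of fibroblasts and of differences along the chromosomes, still address patterns seen in these same data and are not independent of them. Inflammasome and complement genes were not among the fixed lists and were put together after their values were seen, so their medians describe groups picked in part for their differences. Of 17 inflammasome genes, 10 were measured on both arrays, with a median of 0.51. The sensor AIM2 was 39.6-fold higher on the STARD3-shRNA array, the caspase-1 relatives CARD16 and CARD17P were higher by 4.52 and 3.38 on the log2 scale, and CASP1 itself was at least 22.1-fold higher, with near-identical sequence among these last genes. The adaptor PYCARD was 31.0-fold lower, and the sensors NLRP1, CARD8 and IFI16 were at -0.95, -0.57 and -0.09 on the log2 scale. IL1B was at least 8.95-fold higher, CASP4 was at 0.48 and CASP5 at 0.56 on the log2 scale, and the pore-forming GSDMD was at 0.54.

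Of 14 measured complement genes, 4 were at least 2-fold higher, none at least 2-fold lower, and the median was 0.56. C3 was 35.9-fold higher, the C1 proteases C1S and C1R were 15.3-fold and 3.09-fold higher, and the complement inhibitor CD59 was 2.27-fold higher, while the inhibitors CD46 and CD55 were at -0.07 and -0.11. Genes of melanosome biogenesis and transport, also picked afterwards, had a median of 0.01 over 21 genes. That group left out the transport genes MYO5A, RAB27A and MLPH of the pigmentation list, which were at -1.38, -0.81 and -0.88, so it is no contrast to that list.

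The lower STARD3 level was small for a gene targeted by a hairpin. Its size depends on the scaling, and the lowest value over all scalings and the unscaled signal was -0.78, which argues only against array scaling that hides a reduction of 2-fold or more, a limit set after the values were seen. A shift shared by its chromosomal neighbours may account for part of it. The 184 genes within 5 Mb had a median of -0.13 at percentile 0 of random lists, and 26.6% of them were lower than STARD3. An effect of the hairpin and a wrong label on the arrays both remain open, and without a second culture or a protein measurement neither was tested.

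The higher NF-kB targets and cytokines were weighed against fibroblasts mixed into the culture, since the fibroblast list also lay above the random lists. Of the abundant fibroblast collagens COL1A1, COL1A2 and COL3A1, 0 were at least 2-fold higher, and none was well above background on the STARD3-shRNA array, which argues against this source. Of the 16 fibroblast markers, 9 were not measured on both arrays, 3 of the 7 measured were lower (LUM, FBLN1 and MFAP5), and TWIST2 and DCN are shared with melanoma and matrix lists. For an interferon response to the hairpin RNA, the limit was an interferon list median at least 2-fold higher, set after the values were seen. The upper end of the bootstrapped 95% range of that median, over genes only, was 0.54 on the log2 scale. It argues only against a response of that size across the list, and a weaker or partial response stays open. Reduced STARD3, another effect of the hairpin and a difference between separately grown cell populations stay open, because each group is 1 culture.

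A hypothesis for the differences along the chromosomes is that the 2 cell populations differ in regional copy number. The mean product of neighbouring genes' ranked differences, divided by the variance, was 0.205 over 14511 genes, and 1000 shuffled gene orders reached at most 0.025. It was 0.194 when neighbours with similar names were left out and 0.198 after the trend on probe GC content was removed, which argues against base composition of the probes as the source. At a distance of 20 genes it was still 0.152, which argues against shared regulation of directly adjacent genes as the whole source. Runs of windows of the same sign, as on chromosomes 1, 8 and X, also reach beyond 20 genes, but their source was not tested. Regulation of wider domains stays open, DNA was not measured, and the lists that share such windows, cancer-testis antigens and antigen presentation, may carry part of this shift: removing the window medians brought them from 0.99 to 0.67 and from 0.39 to 0.26.

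For the 25 genes at least 16-fold lower, 14 of them by bounds, the surroundings on the array and in the genome were looked at after their values were seen. The spots around them had a median difference of 0.07, and their nearest 10 measured genes one of -0.08. All 4 second probes that were well above background on the control array were also at least 2-fold lower.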
